A study of Homo sapiens with 27 samples.

How the data were processed

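RNA was measured by sequencing in 27 libraries from HuH-7 and JHH-7, both human liver cancer cell lines. The cells carried CRISPR guides, and the groups are named after the guides: a non-targeting control (sgNTC) and guides against KLB (sgKLB), FGFR4 (sgFGFR4), FGFR3 and FGFR4 together (sgFGFR3/4) and, in JHH-7 only, FGFR1, FGFR3 and FGFR4 together (sgFGFR1/3/4). Each of the 9 groups holds 3 libraries, which the labels call biological replicates, so 12 libraries are HuH-7 and 15 are JHH-7. Per the labels' protocols, RNA was total RNA from cultured cells grown with fetal bovine serum. The labels give no sequencing batch or date.

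Per the submitters' processing notes, the authors quantified expression with RSEM against GRCh38. The versions, the aligner and the annotation release are not given in the sources used here. The deposited tables hold 1 value per gene and library for 58735 genes, and the values are FPKM, fragments per kilobase of transcript and per 1000000 assigned fragments (1 M). The unit was read from the values: the columns sum to between 723416 and 822978, where TPM would sum to 1000000, and the values are not whole. All 58735 gene IDs are in GENCODE 29, and 36592 of the symbols equal the current symbol.

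The tables give no read counts. Depth was estimated from the steps between the lowest FPKM values of genes with 1 annotated transcript, which are multiples of the value of 1 fragment. The estimates run from 14.3 M to 27.4 M fragments per library with fragment lengths of 310 to 350 bases. Under these estimates 77.19% to 85.65% of the low values lie within 0.1 of a whole number of fragments. These depths are estimates, so no counting intervals are given.

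What was computed from the deposited FPKM starts with log2(FPKM + 1); the authors' values were not otherwise rescaled. The added 1 shrinks changes of genes with low FPKM, so their log2 changes understate the ratio of the means. Genes with an FPKM of at least 1 in at least 3 libraries of the line were kept, 14716 in HuH-7 and 14987 in JHH-7. Fits over both lines kept 16731 genes. Group means were fitted per line with limma 3.58.1 (trend and robust options, statmod 1.5.0) in R 4.3.3, and contrasts were tested with limma's moderated test, two-sided. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with 0.05 as the threshold.

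Every knockout was compared with sgNTC of its line. In HuH-7, sgFGFR3/4 and sgKLB were each compared with sgFGFR4, and sgKLB with sgFGFR3/4. In JHH-7, sgFGFR3/4 was compared with sgFGFR4, sgFGFR1/3/4 with sgFGFR3/4, and sgKLB with sgFGFR4 and with sgFGFR1/3/4. Line differences of knockouts were tested as an interaction, JHH-7 minus HuH-7, in a fit over all 27 libraries. Overlaps between knockouts of a line were compared with 50 simulations of unchanged groups tested against the same sgNTC libraries. Each gene and library was drawn independently, so the simulations hold no trends shared across the genes of a library.

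Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 26 lists of a comparison and two-sided. Second readings came from camera with an estimated correlation and from fry. The 26 lists hold 454 gene symbols: FGF receptor signalling components, a MAPK pathway activity signature, other MAPK feedback and ETS genes, immediate early genes, bile acid synthesis, bile acid transport and FXR axis, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and PPARA targets, cell cycle and DNA replication, ribosome biogenesis and MYC targets, hepatocyte function, hepatic progenitor and fetal liver, epithelial to mesenchymal transition, epithelial junctions and keratins, glycolysis and hypoxia, ATF4 and amino acid response, unfolded protein response, p53 targets, interferon response, other receptor tyrosine kinases, growth factor ligands, WNT targets, YAP targets, stromal, endothelial and immune markers, and mitochondrially encoded genes. The comparisons, lists, thresholds and the rule for naming genes were chosen before the data were examined.

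That rule names KLB, FGFR1 to FGFR4 and FGF19 in every group. For each knockout against sgNTC it names the 5 largest rises and the 5 largest falls among genes past the threshold with a mean log2(FPKM + 1) of at least 3 and no overlap between the groups. It names up to 4 members of each list described, those with the smallest p in each direction, and the 3 largest rises and falls of each direct comparison and line difference. Genes moving the same way in every knockout of a line add up to 5 in each direction. Pseudogenes and genes with only an ID were passed over. Some genes the rule names are not reported here. Genes outside the rule are said to be chosen after their values were seen.

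The fitting code was tested on simulated data with known changes. For HuH-7 sgKLB against sgNTC (14716 genes), it recovered 43.3% of changes of 0.5, 80.6% of changes of 1 and 100% of changes of 2 on the log2 scale, and 4.49% of its calls were false. For JHH-7 sgKLB against sgNTC (14987 genes), it recovered 37.3%, 80.6% and 95.5% of the same sizes, and 5.33% of its calls were false.

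Alternatives tried were quantile normalization, no filter on low values, a stricter filter (mean log2(FPKM + 1) of at least 3), a pseudocount of 0.1, a change of at least 1 on the log2 scale, the replicate number as a block, a fit of only the groups compared, and leaving out each library. Rescaling to TPM, a lowess correction (span 0.3) of each library for transcript length and GC content, and leaving out the sgFGFR1/3/4 libraries were added later. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.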

Results

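Gene expression was measured in HuH-7 and JHH-7, human hepatocellular carcinoma lines, after CRISPR guides had been directed at KLB or at FGF receptor genes. KLB encodes beta-klotho, the co-receptor that lets the hormone FGF19 signal through FGFR4. The design asks what loss of the co-receptor changes, what loss of FGFR4, FGFR3 and FGFR1 in combination changes, and whether both lines respond alike. HuH-7 gave 12 libraries in 4 groups and JHH-7 15 in 5, with n = 3 biological replicates per group. Editing and target protein were not measured. Estimated depth was 14.3 M to 27.4 M fragments per library. Between 13353 and 14196 genes reached an FPKM of 1 in the HuH-7 libraries, and between 13563 and 13904 in the JHH-7 libraries. Changes are given on the scale of log2(FPKM + 1), which understates changes of genes with low FPKM, and adjusted p-values are from limma.

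The targeted genes were read first. In HuH-7, KLB (ENSG00000134962; GRCh38 chromosome 4, 39406853 to 39451536) fell from a mean of 17.1 ± 1.71 to 6.52 ± 0.633 FPKM (SD, n = 3), a log2 change of -1.26 ± 0.098 (SE; adjusted p 7.32e-06). In JHH-7, KLB went from 15.5 ± 0.286 to 7.25 ± 0.365 FPKM, a log2 change of -0.999 ± 0.083 (adjusted p 4.78e-07).

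FGFR4 (ENSG00000160867; chromosome 5, 177086886 to 177098144) fell in HuH-7 from 238.9 ± 13.6 FPKM to 87.4 ± 1.87 FPKM in sgFGFR4 and to 90.3 ± 4.46 FPKM in sgFGFR3/4, with log2 changes of -1.44 ± 0.071 (adjusted p 2.28e-06) and -1.39 ± 0.071 (adjusted p 1.1e-06). In JHH-7 it fell from 148.2 ± 4.89 FPKM to 69.7 ± 1.89 FPKM in sgFGFR4, to 84.2 ± 12.9 FPKM in sgFGFR3/4 and to 66.9 ± 0.834 FPKM in sgFGFR1/3/4, with adjusted p of 3.8e-05, 0.0001 and 1.88e-07.

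FGFR3 (ENSG00000068078; chromosome 4, 1793293 to 1808872) fell from 117.5 ± 2.82 to 46.7 ± 0.635 FPKM in HuH-7 sgFGFR3/4 (adjusted p 3.6e-07). In JHH-7 it fell from 89.9 ± 6.50 FPKM to 43.9 ± 0.506 FPKM in sgFGFR3/4 and to 34.7 ± 0.361 FPKM in sgFGFR1/3/4 (adjusted p 4.36e-06 and 7.8e-09). FGFR1 (ENSG00000077782; chromosome 8, 38400215 to 38468834) fell from 16.2 ± 2.60 to 9.22 ± 1.36 FPKM in JHH-7 sgFGFR1/3/4, a log2 change of -0.75 ± 0.149 (adjusted p 0.00119). Every library of a group carrying a guide against one of these genes lay below every sgNTC library of its line for that gene, so the labels match the transcripts. All targeted transcripts stayed detectable.

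Guides also changed family members they did not target. FGFR2 (ENSG00000066468; chromosome 10, 121478334 to 121598458) rose in JHH-7 from 10.7 ± 0.634 FPKM to 17.8 ± 2.96 FPKM in sgKLB (adjusted p 0.000705) and to 19.6 ± 2.97 FPKM in sgFGFR1/3/4 (adjusted p 0.000151), while in HuH-7 it stayed below 1 FPKM in every group mean. FGFR3 rose by 0.38 ± 0.066 in JHH-7 sgKLB (adjusted p 0.000435), and KLB rose by 0.38 ± 0.083 in JHH-7 sgFGFR1/3/4 (adjusted p 0.00223). FGF19 (ENSG00000162344; chromosome 11, 69698232 to 69704642), the ligand, moved in opposite directions in the lines. In HuH-7 it rose from 8.33 ± 0.496 FPKM to 19.1 ± 1.09 FPKM in sgKLB (adjusted p 3.62e-05) and to 12.6 ± 1.66 FPKM in sgFGFR3/4 (adjusted p 0.00755), and was at 8.52 ± 0.510 FPKM in sgFGFR4 (adjusted p 0.889). In JHH-7 it fell from 177.1 ± 13.6 FPKM to 45.8 ± 1.91 in sgKLB, 111.8 ± 12.2 in sgFGFR4, 121.6 ± 10.4 in sgFGFR3/4 and 43.9 ± 1.26 in sgFGFR1/3/4, with adjusted p of 1.01e-09, 0.00107, 0.00345 and 2.9e-09.

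**Figure D1:**
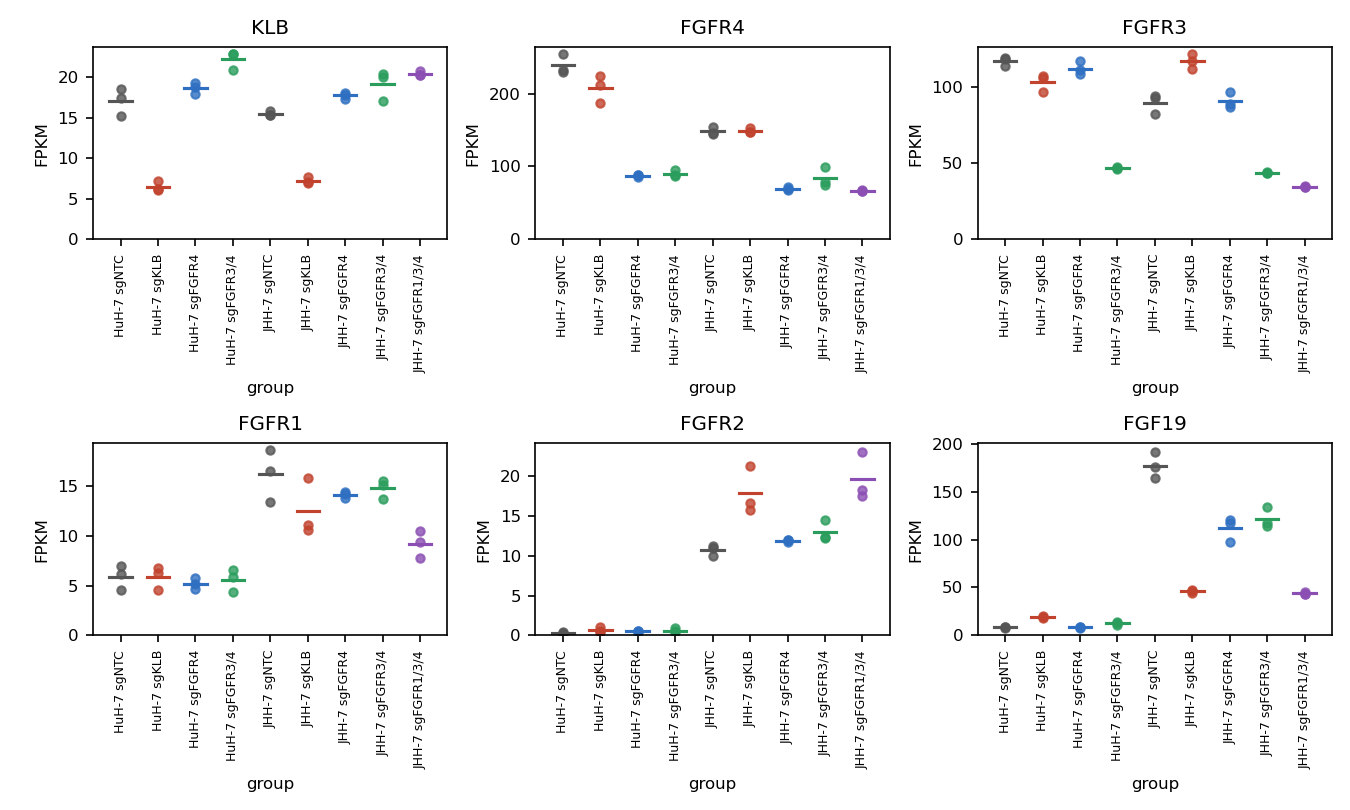
FPKM of KLB, FGFR4, FGFR3, FGFR1, FGFR2 and FGF19 in each library (points) with the group mean (line), by guide and cell line. FGF19 is higher in HuH-7 sgKLB (19.1 FPKM) than in its sgNTC (8.33 FPKM) and lower in JHH-7 sgKLB (45.8 FPKM) than in its sgNTC (177.1 FPKM).

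HuH-7 sgKLB moved genes both ways. The plasmin inhibitor SERPINF2 rose by 1.93 ± 0.079 (adjusted p 1.33e-07), the paraoxonase PON1 by 1.83 ± 0.205 (adjusted p 0.000105), the amino acid transport partner CLTRN by 1.78 ± 0.116 (adjusted p 2.51e-06) and ERP27 by 1.69 ± 0.123 (adjusted p 4.8e-06). ETV4, a transcription factor induced by FGF and ERK signalling, fell from 52.4 ± 7.10 to 17.7 ± 0.795 FPKM (log2 change -1.51 ± 0.101, adjusted p 2.73e-06). LGALS14 fell by 1.65 ± 0.295, NNMT at -1.46 ± 0.288 and SYT12 at -1.39 ± 0.132, with adjusted p of 0.00232, 0.00442 and 3.31e-05.

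Of 14716 genes, 2591 passed the threshold in this comparison, 1322 rising and 1269 falling, and 224 of them changed by at least 1 on the log2 scale (159 up, 65 down). Rescaling the libraries to a common sum (TPM) left the total near this but changed the split to 1725 rising and 969 falling, and after the length and GC correction it was 1472 and 1728. Small changes therefore have no firm direction here, and FGFR3, at -0.18 ± 0.057 (adjusted p 0.0429), lost its call when any library but sgKLB replicate 1 was left out (adjusted p 0.0448 to 0.154).

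Where a second count follows in brackets it is adjusted over the list alone. The MAPK pathway activity signature, transcripts that follow ERK output, fell: 7 of 9 measured members fell and 0 rose (8 and 0 when adjusted over the list alone), with a median of -1.01 and a list p of 1.43e-08. The feedback inhibitor SPRY4 fell by 1.26 ± 0.090 (adjusted p 4.29e-06). Other MAPK feedback and ETS genes had 5 of 10 members falling and 1 rising (6 and 1 over the list alone, median -0.52, p 0.00174). All but 1 of the 30 cell cycle and DNA replication genes fell (29, and all 30 adjusted over the list alone, median -0.74, p 5.09e-31). Ribosome biogenesis and MYC targets had 15 of 22 falling and 0 rising (19 and 0 over the list alone, median -0.53, p 3.61e-14).

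YAP targets fell in 5 of 12 cases with 0 rising (8 and 1 over the list alone, median -0.38, p 1.52e-05). Glycolysis and hypoxia genes went both ways, 10 falling and 3 rising of 19 (10 and 4 over the list alone, median -0.33, p 0.00398). The unfolded protein response had 8 of 14 falling (8 over the list alone, median -0.27, p 0.00169), and cholesterol synthesis 8 of 24 falling (9 falling and 1 rising over the list alone, median -0.13, -0.06 with TPM, p 0.00202).

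Hepatocyte genes rose in 13 of 24 cases with 0 falling (14 and 2 over the list alone, median 0.46, p 5.83e-09). Fatty acid oxidation and PPARA targets had 9 of 17 rising and 0 falling under either adjustment (median 0.35, p 8.71e-08). Bile acid synthesis had 4 of 9 rising and 1 falling under either adjustment (median 0.38, p 0.00328). CYP7A1, the classical gate enzyme of the pathway, was below the expression filter in both lines. Interferon response genes had 6 of 14 rising and 1 falling (10 and 1 over the list alone, median 0.33, p 0.00355). These 12 lists all held with an estimated correlation (p from 6.47e-05 for the cell cycle to 0.0476 for cholesterol synthesis).

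Loss of FGFR4 alone in HuH-7 gave a weaker profile, and the targeted gene is its only firm call. FGFR4 kept an adjusted p of 4.57e-05 or less whichever library was left out. The chromatin remodeller ATRX (7.64 ± 3.70 to 22.7 ± 4.96 FPKM) rose by 1.51 ± 0.316 and AKAP9 by 1.46 ± 0.302, both with adjusted p 0.0393. GOLGB1 rose by 1.17, ATM by 1.08 and KIAA1109 by 1.07 (adjusted p 0.0497, 0.0491 and 0.0455). Thymidine kinase TK1 fell by 0.70 ± 0.105 (adjusted p 0.0301), and PSRC1, MRPL17 and PIMREG were at -0.75, -0.65 and -0.64 (adjusted p 0.0455, 0.0376 and 0.0476).

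In all, 546 genes passed (304 rising, 242 falling) and 3976 had an unadjusted p under 0.05. The count rested on single libraries: it was 4 without sgNTC replicate 2, 2 without sgNTC replicate 3, 1 without sgFGFR4 replicate 1 or replicate 2, 3 without sgFGFR4 replicate 3, and 1224 without sgNTC replicate 1. All 9 other genes just named lost their calls without sgNTC replicate 2, sgNTC replicate 3, sgFGFR4 replicate 1 or sgFGFR4 replicate 2 (adjusted p up to 0.181). It was also 96 after quantile normalization, and 1 without the filter on low values, with the replicate number as a block, or in a fit of these 2 groups alone. With TPM the split was 441 rising and 125 falling, after quantile normalization 41 and 55, and after the length and GC correction 107 and 257. Log2 changes followed GC content across genes (Spearman -0.505, genes not being independent) and transcript length (0.22): rising genes had a median length of 4384 bases and falling genes 2414.5 bases.

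Of the lists, 7 passed in this comparison and 4 of them held with an estimated correlation. Cell cycle genes had 14 of 30 falling and 0 rising (22 and 1 over the list alone, median -0.28, p 4.16e-12, estimated 0.00216). Cholesterol synthesis had 9 of 24 falling (14 falling and 2 rising over the list alone, median -0.24, p 2.99e-07, estimated 0.0103). Ribosome biogenesis had 9 of 22 falling (11 over the list alone, median -0.24, p 2.9e-05, estimated 0.00858). Glycolysis had 5 of 19 falling (12 falling and 1 rising over the list alone, median -0.26, p 4.95e-06, estimated 0.00858). The MAPK signature (1 of 9 falling; 3 over the list alone, median -0.26, p 0.00319), the unfolded protein response (5 of 14 falling; 6 falling and 1 rising over the list alone, median -0.11, p 0.00387) and mitochondrially encoded genes (0 of 13 called by limma under either adjustment, median -0.06, p 0.00479) gave 0.0796, 0.102 and 0.321. With TPM the medians of cholesterol synthesis, ribosome biogenesis and the unfolded protein response shrank to -0.15, -0.16 and -0.03, and the mitochondrial one turned to 0.03 (0.05 after quantile normalization).

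Loss of FGFR3 and FGFR4 together in HuH-7 shared the leading changes of KLB loss. CLTRN rose by 1.65 ± 0.116 (adjusted p 1.93e-05), ERP27 by 1.47 (adjusted p 4.34e-05) and AKAP9 by 1.65 (adjusted p 0.00488). LGALS14 fell by 1.69 (adjusted p 0.0039), SLC4A11 at -1.31 (adjusted p 0.00541) and NNMT at -1.26 (adjusted p 0.0136). NNMT lost its call without sgNTC replicate 3 or sgFGFR3/4 replicate 3 (adjusted p 0.00667 to 0.0587 over the libraries left out). RAP2C rose by 1.79 ± 0.518 (adjusted p 0.0416) and lost its call without any library but sgFGFR3/4 replicate 1 (0.00471 to 0.132). KLB itself rose by 0.36 ± 0.098 (adjusted p 0.0277), a call lost without sgNTC replicate 2 or 3 or sgFGFR3/4 replicate 1 or 3 (0.0235 to 0.101).

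The threshold was passed by 2371 genes, 1309 rising and 1062 falling, and with TPM by 2191 rising and 632 falling. Falling genes were the majority after quantile normalization (881 and 970) and the length and GC correction (1017 and 1445). The count dropped to 1255 without sgNTC replicate 3, 1345 without sgFGFR3/4 replicate 1 and 1150 without sgFGFR3/4 replicate 3, and to 999 in a fit of these 2 groups alone and 1433 without the filter on low values. Spearman correlation with GC content across genes was -0.315.

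Among 14 lists past the threshold, the cell cycle had 22 of 30 falling and 0 rising (24 and 0 over the list alone, median -0.49, p 7.04e-20). The MAPK signature had 6 of 9 falling under either adjustment (median -0.56, p 1.08e-06). Ribosome biogenesis had 13 of 22 falling (14 over the list alone, median -0.37, p 1.08e-09), glycolysis 11 falling and 2 rising of 19 (11 and 3, median -0.41, p 1.06e-05), cholesterol synthesis 9 of 24 falling (11 falling and 1 rising, median -0.20, p 0.00013), and the unfolded protein response 7 of 14 falling (8 falling and 2 rising, median -0.20, p 0.000883), the last 2 medians both -0.09 with TPM and -0.13 and -0.07 after quantile normalization. Hepatocyte genes had 13 of 24 rising and 2 falling (15 and 3, median 0.34, p 2.72e-05). Fatty acid oxidation had 7 of 17 rising (11, median 0.36, p 1.2e-05) and bile acid synthesis 4 of 9 rising (5, median 0.38, p 0.0014). YAP targets had 5 of 12 falling under either adjustment (median -0.10, p 0.0014), but the median was 0.00 with TPM.

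With an estimated correlation 10 of the 14 held. Other MAPK feedback genes (2 of 10 falling, 1 rising under either adjustment, median -0.30, p 0.0224), fatty acid synthesis (2 rising, 2 falling of 15; 3 and 6 over the list alone, median -0.16, p 0.0404), the ATF4 list (4 falling, 1 rising of 19 under either adjustment, median -0.10, p 0.0219) and mitochondrially encoded genes (4 of 13 falling; 8 over the list alone, median -0.14, p 0.000148) gave 0.0694, 0.254, 0.114 and 0.121. With TPM the ATF4 median was 0.01 and that of fatty acid synthesis -0.05, and after quantile normalization the mitochondrial median was 0.02.

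Direct comparisons in HuH-7 separate the knockouts. Between sgFGFR3/4 and sgFGFR4, 238 genes differed (150 rising, 88 falling). MPP1 rose by 1.00 (adjusted p 0.000771) and SERPINF2 by 0.95 (adjusted p 0.000172). FGFR3 fell by 1.25 (adjusted p 9.18e-07). SLC4A11 at -1.15, XAGE2 at -0.85 and FGF19 at 0.50 passed (adjusted p 0.0394, 0.0265 and 0.0394) but each lost its call in 5 of the 6 fits that left out 1 library (adjusted p up to 0.155; FGF19 kept it without sgFGFR3/4 replicate 3, SLC4A11 without sgFGFR4 replicate 1 and XAGE2 without sgFGFR3/4 replicate 1). The count fell with any library left out: 133, 106 and 99 without sgFGFR4 replicates 1, 2 and 3, and 113, 124 and 142 without sgFGFR3/4 replicates 1, 2 and 3. It was 134 without the low-value filter, 119 with replicate blocks, 87 with these groups alone and 440 after the length and GC correction.

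Lists moved further in the direction of KLB loss: the cell cycle (3 of 30 falling; 12 over the list alone, median -0.22, p 1.63e-12), the MAPK signature (2 of 9; 6, median -0.39, p 1.24e-05), ribosome biogenesis (1 of 22; 7, median -0.20, p 4.25e-07) and YAP targets (4 of 12; 6, median -0.25, p 1.29e-05) fell, and hepatocyte genes (8 of 24 rising; 12 rising and 1 falling, median 0.20, p 2.04e-09), fatty acid oxidation (5 of 17; 7, median 0.18, p 8.35e-08) and bile acid synthesis (2 of 9; 4, median 0.28, p 0.000602) rose, all holding with an estimated correlation (p 0.0164 or less). Other MAPK feedback genes (p 0.0438) and immediate early genes (p 0.0156) did not hold (0.114 and 0.181).

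Set directly against sgFGFR4, HuH-7 sgKLB differed in 2463 genes (1044 higher, 1419 lower). The majority turned to 1384 higher and 1206 lower after quantile normalization and to 1245 and 1103 after the length and GC correction. SERPINF2 was higher by 1.61, TNFSF10 by 1.48 and FGF19 by 1.08 (adjusted p 9.11e-07, 0.0058 and 8.59e-05). Lower were CENPF at -1.63, ATRX at -1.55 and SMC4 at -1.43 (adjusted p 0.0043, 0.00746 and 0.00542). Without sgKLB replicate 1 or 3 the count was 1401 or 1332, and without sgFGFR4 replicate 2 or 3 it was 1221 or 1493. Cell cycle genes were lower in 28 of 30 cases (29 over the list alone, median -0.53, p 2.81e-19), the MAPK signature in 8 of 9 (median -0.67, p 7.8e-06), ribosome biogenesis in 14 of 22 (15, median -0.34, p 8.33e-08) and YAP targets in 7 of 12 (9, with 1 higher, median -0.54, p 7.51e-06). Hepatocyte genes were higher in 13 of 24 (14, with 1 lower, median 0.44, p 7.39e-10) and fatty acid oxidation in 7 of 17 (8, median 0.15, p 1.08e-06), and these 6 held with an estimated correlation (p 0.0116 or less). Other MAPK feedback and bile acid synthesis (both 0.0558), mesenchymal transition genes (0.155) and interferon genes (0.0815) passed only at the preset correlation (p 0.0129, 0.0129, 0.0162 and 0.031).

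Against sgFGFR3/4, sgKLB differed in only 81 genes (32 higher, 49 lower), with 2564 at an unadjusted p under 0.05. Here too log2 changes followed GC content across genes (Spearman 0.421). FGFR4 was higher by 1.19, FGFR3 by 1.13 and KLB lower at -1.63, the guide targets themselves (adjusted p 6.91e-06, 2.98e-06 and 6.91e-06). CHD7 at 0.90, C2orf74 at -1.03, ERCC6L2 at -0.96 and FGF19 at 0.58 had adjusted p of 0.0419, 0.0278, 0.0432 and 0.0419. Each lost its call without any sgKLB library or without sgFGFR3/4 replicate 3 (adjusted p up to 0.194). The count was 14, 9 and 12 without sgKLB replicates 1, 2 and 3, and 10, 181 and 3 without sgFGFR3/4 replicates 1, 2 and 3. Cell cycle genes were still lower (6 of 30; 23 over the list alone, median -0.26, p 1.41e-16, estimated 0.00069), and hepatocyte genes (4 of 24; 9 higher and 1 lower, median 0.16, p 9.72e-08), fatty acid oxidation (median 0.14), ribosome biogenesis (median -0.15) and YAP targets (median -0.26) also differed, each with an estimated p of 0.0195. The MAPK signature (median -0.25, p 0.00136, estimated 0.0551), glycolysis (p 0.00755, estimated 0.0556), mesenchymal transition (p 0.00153, estimated 0.0789), the ATF4 list (p 0.0427, estimated 0.173) and mitochondrial genes (p 0.000388, estimated 0.173) did not hold.

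Across HuH-7, 105 genes rose and 194 fell in all 3 knockouts, where simulated unchanged groups gave 0. CLTRN rose by 0.92 to 1.78, ERP27 by 0.79 to 1.69, the glucuronosyltransferase UGT2B4 by 0.74 to 1.47, SERPINF2 by 0.32 to 1.93 and KLHL24 by 0.94 to 1.19. ETV4 ranged from -1.51 to -0.41, H19 from -1.11 to -0.54, CDC45 from -1.17 to -0.54, PIMREG from -1.23 to -0.64 and RRM2 from -1.15 to -0.59. Their sgFGFR4 part carries the limits given above. sgKLB and sgFGFR3/4 shared 707 rising and 778 falling genes with 1 in opposite directions, where 118 and 91.6 were expected of independent lists and 0.02 was simulated. Covariance of their log2 changes was 0.0954, against 0.0295 simulated from the shared sgNTC libraries alone. sgKLB and sgFGFR4 shared 117 and 200 with 7 opposite (27.3 and 20.9 expected, 0 simulated). Their covariance was 0.05 against 0.0293 simulated, but their correlation across genes (0.405) lay below the simulated 0.502.

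**Figure D2:**
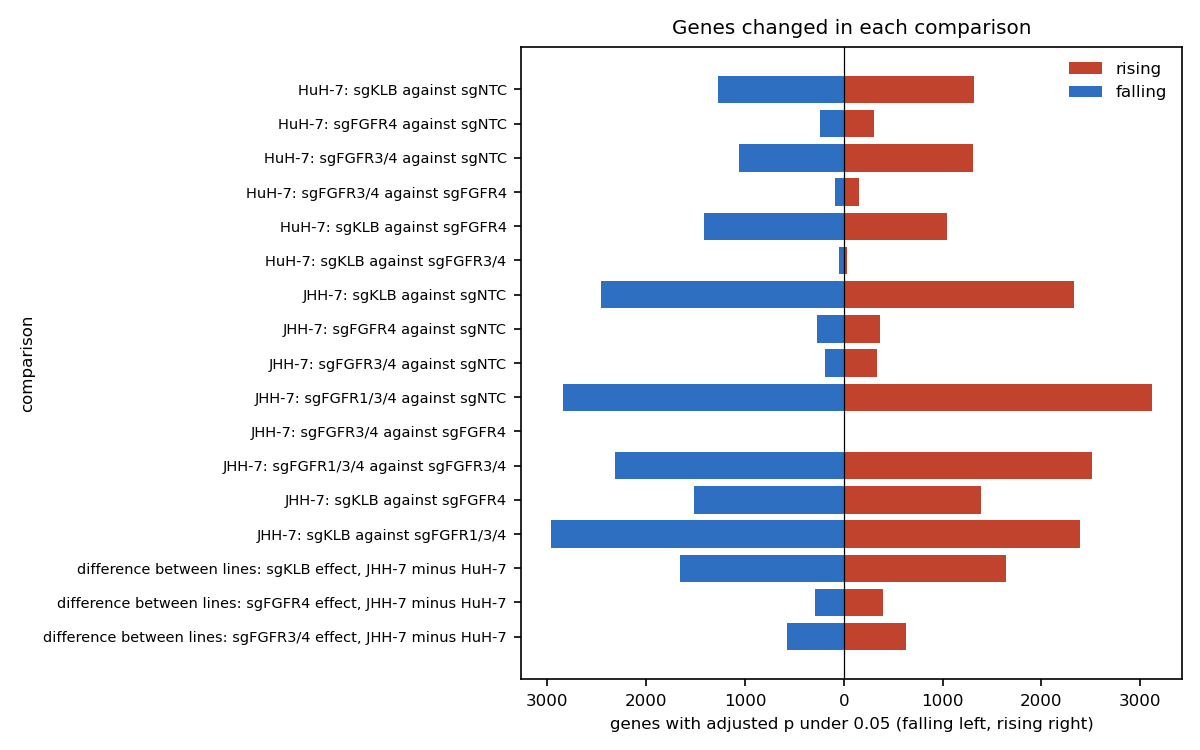
Number of genes past the threshold in each comparison, rising to the right and falling to the left, by cell line and for the line differences. JHH-7 sgFGFR1/3/4 against sgNTC has the most (5963 genes), and JHH-7 sgFGFR3/4 against sgFGFR4 has 2.

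Loss of KLB changed JHH-7 more than HuH-7. GSTA1, a glutathione transferase of hepatocytes, rose from 8.55 ± 2.07 to 130.7 ± 3.72 FPKM (log2 change 3.81 ± 0.137, adjusted p 3.17e-10). GSTA2 rose by 3.17 (adjusted p 1.78e-09), the steroid and bile acid sulfotransferase SULT2A1 by 3.16 (adjusted p 7.04e-10) and gastrin (GAST) by 2.69 ± 0.265 (adjusted p 2.61e-06). IGFBP1 fell from 51.1 ± 6.54 to 1.21 ± 0.285 FPKM (-4.56 ± 0.286, adjusted p 2.95e-08) and GDF15 from 1513 ± 199.9 to 81.4 ± 8.47 FPKM (-4.20 ± 0.175, adjusted p 6.84e-10). The mTORC1 inhibitor DDIT4 fell by 4.02 (adjusted p 1.09e-09), with DUSP5 at -3.45 (adjusted p 6.07e-11). GSTA1 and GSTA2 are close copies, and reads could be divided between them.

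Of 14987 genes, 4781 passed (2326 rising, 2455 falling; 2435 and 2355 after quantile normalization) and 864 changed by at least 1 on the log2 scale (488 up, 376 down). All 18 measured genes of the ATF4 and amino acid response list fell under either adjustment (median -2.01, p 9.47e-23, estimated 0.00639). The serine synthesis enzyme PSAT1 went from 305.6 ± 13.0 to 92.6 ± 2.24 FPKM (-1.71 ± 0.061, adjusted p 3.17e-10), and the amino acid transporter SLC7A5 fell by 2.08. The MAPK signature had 7 of 9 falling under either adjustment (median -1.74, p 5.29e-07). Other MAPK feedback genes had 5 of 11 falling (6, median -0.59, p 0.000865), immediate early genes 9 of 12 falling under either adjustment (median -1.01, p 2.55e-07), and ribosome biogenesis 19 of 22 falling under either adjustment (median -0.61, p 1.34e-09).

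Hepatocyte genes rose in 22 of 27 cases with 2 falling under either adjustment (median 0.75, p 2.33e-12). Cholesterol synthesis, which fell in HuH-7, had 18 of 24 rising and 1 falling (19 and 1, median 0.80, p 4.32e-11). Bile acid synthesis had 7 of 10 rising and 1 falling (8 and 1, median 1.10, p 1.44e-05). Fatty acid synthesis had 9 of 15 rising and 1 falling under either adjustment (median 0.63, p 0.000149), and fatty acid oxidation 10 of 16 rising and 1 falling (11 and 1, median 0.51, p 7.08e-06). WNT targets had 7 of 13 rising (8, median 0.45, p 0.000125), and interferon genes 5 of 19 rising under either adjustment (median 0.23, p 0.00952). These lists and the falling ones all held with an estimated correlation (p 0.027 or less). Cell cycle genes rose in 15 of 30 cases with 1 falling under either adjustment (median 0.33, p 2.11e-05), but the estimated correlation gave 0.236. Mitochondrially encoded genes (11 of 13 rising; 13 over the list alone, median 0.53, p 2.83e-07) gave 0.18.

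FGFR4 loss in JHH-7 moved the same leading genes by less. SULT2A1 rose by 1.33 ± 0.136 and GSTA1 by 1.27 ± 0.137 (both adjusted p 0.000349), SPTLC3 by 1.22 (0.000717) and AADAC by 1.28 (0.0101). IGFBP1 fell by 2.23 ± 0.286 (adjusted p 0.000928), GDF15 at -1.66 and the cell cycle inhibitor CDKN2B at -1.33 (both 0.000349) and BEX2 at -1.21 (0.0218). AADAC lost its call without sgFGFR4 replicate 1 (0.011 to 0.0613 over the libraries left out). BEX2 lost it without sgNTC replicate 1 or 2 or sgFGFR4 replicate 1 or 2 (0.00142 to 0.0989). In total 637 genes passed (362 rising, 275 falling). That count was 418 without sgNTC replicate 1, 276 without sgNTC replicate 2, 222 without sgFGFR4 replicate 1 and 267 without sgFGFR4 replicate 2. It was 337 without the low-value filter, 409 without the sgFGFR1/3/4 libraries and 87 with these groups alone.

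For this knockout 11 lists passed at the preset correlation and 0 with an estimated one in camera. The ATF4 list had 9 of 18 falling and 0 rising (14 over the list alone, median -0.48, p 6.68e-13), and the cell cycle 9 of 30 rising and 0 falling (20, median 0.30, p 1.18e-14). Hepatocyte genes had 7 of 27 rising (15 rising and 4 falling, median 0.23, p 0.000415), immediate early genes 4 of 12 falling (6, median -0.35, p 1.84e-05) and other MAPK feedback genes 1 of 11 falling (DUSP5 at -1.16, median -0.16, p 0.0129), and all 5 gave 0.0627. Bile acid synthesis (3 of 10 rising; 5, median 0.34, p 0.000415) gave 0.0541, the MAPK signature (3 of 9 falling; 4, median -0.17, p 0.00597) 0.0762, and fatty acid oxidation (1 of 16 rising; 4 rising and 1 falling, median 0.10, p 0.0226) 0.0682. Cholesterol synthesis (median 0.13, p 0.0389), WNT targets (median 0.18, p 0.0129) and mitochondrial genes (median 0.29, p 5.03e-10) gave 0.266, 0.129 and 0.132.

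JHH-7 sgFGFR3/4 was close to sgFGFR4. GSTA1 rose by 1.63 ± 0.137 (adjusted p 2.66e-05), SULT2A1 by 1.41 (7.43e-05), PLCXD2 by 1.37 (0.00172) and GSTA2 by 1.27 (0.00033). IGFBP1 fell by 1.90 ± 0.286 (adjusted p 0.00214), CDKN2B at -1.71 (2.66e-05), GDF15 at -1.43 (0.00042) and the histone gene HIST2H2AA4, which has a near-identical copy, at -1.37 (0.00481). The threshold was passed by 529 genes, 336 rising and 193 falling. Without sgNTC replicate 1, 2 or 3 the count was 297, 346 or 260, and without sgFGFR3/4 replicate 3 it was 259. It was 263 without the low-value filter, 294 without the sgFGFR1/3/4 libraries and 128 with these groups alone.

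Here 15 lists passed and 8 held with an estimated correlation. Hepatocyte genes had 9 of 27 rising (14 rising and 1 falling over the list alone, median 0.38, p 1.64e-10, estimated 0.00429). Bile acid synthesis had 5 of 10 rising (6, median 0.56, p 3.83e-07, estimated 0.00429) and fatty acid oxidation 4 of 16 rising (median 0.16, p 2.19e-05, estimated 0.00625). Falling lists were the MAPK signature (3 of 9; 5, median -0.30, p 1.82e-05) and immediate early genes (5 of 12, median -0.33, p 4.07e-07), both at an estimated 0.017, other MAPK feedback genes (2 of 11, median -0.17, p 0.00262, estimated 0.0283), the unfolded protein response (3 of 14; 5 falling and 1 rising, median -0.17, p 0.00384, estimated 0.0286) and FGF receptor signalling components (4 of 15; 4 falling and 1 rising, median -0.12, p 0.00684, estimated 0.035), which contain FGFR3, FGFR4 and FGF19. The ATF4 list (3 of 18 falling; 11, median -0.32, p 1.16e-08) and the cell cycle (3 of 30 rising; 11, median 0.22, p 1.64e-10) both gave 0.0728. Cholesterol synthesis (median 0.22, p 0.000178), fatty acid synthesis (median 0.09, p 0.022), ribosome biogenesis (median -0.15, p 2.19e-05), WNT targets (median 0.10, p 0.0446) and mitochondrial genes (median 0.25, p 3.06e-09) gave 0.0683, 0.0663, 0.0971, 0.18 and 0.11.

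Compared with sgFGFR4 directly, sgFGFR3/4 differed in 2 of 14987 JHH-7 genes in limma, with 766 at an unadjusted p under 0.05. FGFR3 itself fell by 1.03 ± 0.066 (adjusted p 3.43e-06). The other is AP003119.2, which the naming rule passes over and which is given here after its value was seen: it rose by 1.75 ± 0.195 (adjusted p 0.00245). The count was 4 without sgFGFR4 replicate 2 and 1 without sgFGFR3/4 replicate 1 or 2. At the preset correlation 8 lists passed, hepatocyte genes most clearly (0 of 27 called over all genes, 5 rising over the list alone, median 0.12, p 2.4e-06), and 0 held in camera with an estimated correlation (0.0514 for hepatocyte genes).

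JHH-7 sgFGFR1/3/4 had the most genes past the threshold of the comparisons with sgNTC. SPTSSB rose by 3.47 ± 0.624 (adjusted p 0.000786), the YAP-responsive repeat protein ANKRD1 from 29.4 ± 3.28 to 165.7 ± 6.55 FPKM (2.46 ± 0.089, adjusted p 1.46e-09), SULT2A1 by 2.29 (4.14e-08), PI3 by 2.27 (4.6e-06) and TAGLN by 2.26 (6.35e-05). ANGPTL8, a lipoprotein lipase regulator, fell from 261.7 ± 67.5 to 13.0 ± 1.40 FPKM (-4.21 ± 0.257, adjusted p 6.01e-08). IGFBP1 fell by 4.18 (1.18e-07), MEF2B at -3.93 (1.49e-07), DDIT4 at -3.87 and GDF15 at -3.68 (both 5.97e-09). The threshold was passed by 5963 genes (3119 rising, 2844 falling; 2733 and 2783 after the length and GC correction), 814 of them changed by at least 1 on the log2 scale. The 3 sgFGFR1/3/4 libraries stood apart as a set. Their FPKM sums lay between 734241 and 734381, where other JHH-7 libraries ran from 745482 to 791744, and log2 changes followed GC content across genes (Spearman -0.419). Their replicates also lay closer together: the SD of log2 differences between 2 replicates was 0.215 to 0.23, against 0.237 to 0.373 in other JHH-7 groups, and squared differences were 5.47 to 5.57 times those expected from counting fragments, against 7.9 to 31.8. The p-values of this group hold only if its libraries are independent replicates, as labelled.

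At the preset correlation 9 lists passed here, and 0 did with an estimated one in camera. All 18 ATF4 list members fell under either adjustment (median -1.72, p 5.24e-20, estimated 0.0685). Cell cycle genes rose in 27 of 30 cases with 1 falling (28 and 1, median 0.68, p 6e-12). WNT targets had 7 of 13 rising (8 rising and 1 falling, median 0.82, p 0.00664). Bile acid synthesis had 6 of 10 rising and 1 falling (7 and 1, median 0.59, p 0.00801), immediate early genes 8 of 12 falling and 2 rising (median -0.66, p 0.00134), FGF receptor components 7 of 15 falling and 3 rising (median -0.19, p 0.0307) and other MAPK feedback genes 3 of 11 falling and 1 rising (median -0.29, p 0.0366), and like the cell cycle and WNT lists they gave 0.101. Cholesterol synthesis (17 of 24 rising, 4 falling, median 0.39, p 0.00245) and YAP targets (7 of 12 rising, 2 falling, median 0.70, p 0.0124), gave 0.122. The MAPK signature had 5 of 9 falling and 2 rising (median -0.79) and did not pass (p 0.131): ETV4 fell by 1.00 while CCND1 rose by 0.66.

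Against sgFGFR3/4, the sgFGFR1/3/4 libraries differed in 4826 genes (2514 rising, 2312 falling; 3023 and 1895 with TPM, 2395 and 2536 after quantile normalization, 2045 and 2109 after the length and GC correction). FGFR1 fell by 0.63 ± 0.149 (adjusted p 0.00537) and FGF19 at -1.45 ± 0.087 (1.38e-07). FGFR3 fell by 0.33 (0.00177), and FGFR4 at -0.32 (0.00945), a call lost after the length and GC correction (0.34). ANKRD1 rose by 2.21 (6.66e-09) and TAGLN by 2.15 (0.000188), and ANGPTL8 fell by 3.55 (8.07e-07), MEF2B at -3.22 (2.48e-06) and CHAC1 at -3.17 (3.29e-06). EXOC6 rose by 1.95 ± 0.655 (0.0389), a call lost in every fit without 1 library except that without sgFGFR3/4 replicate 3 (0.0274 to 0.126). All 18 ATF4 genes fell under either adjustment (median -1.27, p 1.37e-21, estimated 0.0533). The cell cycle (22 of 30 rising, 1 falling under either adjustment, median 0.41, p 1.19e-07), ribosome biogenesis (14 of 22 rising, 3 falling under either adjustment, median 0.35, p 0.00258), WNT targets (5 of 13 rising, median 0.41, p 0.0428) and YAP targets (8 of 12 rising, 2 falling, median 0.57, p 0.00258) rose and mitochondrial genes fell (7 of 13; 10, median -0.30 but 0.00 after quantile normalization, p 0.000344) at the preset correlation, and gave 0.242, 0.323, 0.242, 0.218 and 0.336 with an estimated one.

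Set against sgFGFR4, JHH-7 sgKLB differed in 2900 genes (1389 higher, 1511 lower; 1441 and 1373 with TPM, 1543 and 1401 after quantile normalization). GSTA1 was higher by 2.54 (adjusted p 2.91e-08) and GSTA2 by 2.18 (2.41e-07), while lower values were seen for DDIT4 at -3.15 (4.79e-08), CHAC1 at -2.84 (7.08e-06) and STC2 at -2.68 (1.63e-07). Haptoglobin (HP) was higher by 2.65 ± 0.861 (0.0489), a call lost in every fit without 1 library except that without sgFGFR4 replicate 2 (0.0138 to 0.159). FGF19 was lower (-1.26 ± 0.087, 2.35e-07). Of 14 lists past the threshold 12 held with an estimated correlation, among them the ATF4 list (18 of 18 lower, median -1.64, p 2.09e-27, estimated 0.00333), hepatocyte genes (20 of 27 higher, median 0.59, p 2.21e-16, estimated 0.00154), cholesterol synthesis (18 of 24 higher, 1 lower; 20 and 1, median 0.60, p 1.28e-15, estimated 0.00194) and the MAPK signature (7 of 9 lower, median -1.10, p 2.96e-08, estimated 0.00275). YAP targets (p 0.0231) and mitochondrial genes (p 0.00709) gave 0.14 and 0.45.

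Between sgKLB and sgFGFR1/3/4, 5346 genes differed (2387 higher and 2959 lower in sgKLB; 2076 and 3281 with TPM). SLC22A7 was higher by 2.73 (adjusted p 1.44e-07), GAST by 2.18 (4.02e-05) and AGXT by 2.11 (2.71e-06). Lower were ANKRD1 at -2.93 (1.28e-10), EXOC6 at -2.43 (0.0125) and CXCL8 at -2.20 (2.76e-07), and FGF19 did not differ detectably (0.06 ± 0.087, adjusted p 0.627). The MAPK signature was lower in 9 of 9 cases (median -0.84, p 2.18e-07, estimated 0.00565), and hepatocyte genes were higher in 20 of 27 with 2 lower (21 and 3, median 0.65, p 1.32e-11), fatty acid synthesis in 11 of 15 with 2 lower (12 and 2, median 0.65, p 1e-06) and fatty acid oxidation in 10 of 16 (12, median 0.41, p 2.09e-06), each with an estimated 0.00274. Ribosome biogenesis (18 of 22 lower; 19, median -0.70, p 4.99e-11) and YAP targets (8 of 12 lower, median -0.59, p 4.36e-05) gave 0.0257 and bile acid synthesis (median 0.49, p 0.00811) 0.0451. Immediate early genes, cholesterol synthesis, the cell cycle and mitochondrial genes passed (p 0.00197, 6.73e-05, 2.09e-06 and 5.56e-08) but gave 0.104, 0.0645, 0.196 and 0.183. The ATF4 list was not separated (median -0.11, p 0.108).

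Across JHH-7, 183 genes rose and 127 fell in all 4 knockouts (0 simulated). GSTA1 rose by 1.27 to 3.81, SULT2A1 by 1.33 to 3.16, GSTA2 by 0.99 to 3.17 and UGT2B10 by 1.05 to 2.31. IGFBP1 ranged from -4.56 to -1.90, GDF15 from -4.20 to -1.43, DDIT4 from -4.02 to -0.71 and DUSP5 from -3.45 to -1.12. DDIT4 in sgFGFR3/4 lost its call whichever library was left out (adjusted p 0.0919 to 0.132, from 0.0474), and in sgFGFR4 without sgNTC replicate 2 or sgFGFR4 replicate 1 or 2 (0.0204 to 0.0893, from 0.016). sgKLB and sgFGFR1/3/4 shared 1262 rising and 1374 falling genes with 230 opposite (484 and 466 expected, 0 simulated), with a covariance of 0.185 against 0.0308 simulated. sgKLB shared 335 rising and 264 falling genes with sgFGFR4 (56.2 and 45 expected) and 325 and 186 with sgFGFR3/4 (52.1 and 31.6 expected), 0 simulated for either, with covariances of 0.108 and 0.112 against 0.0306 simulated.

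**Figure D3:**
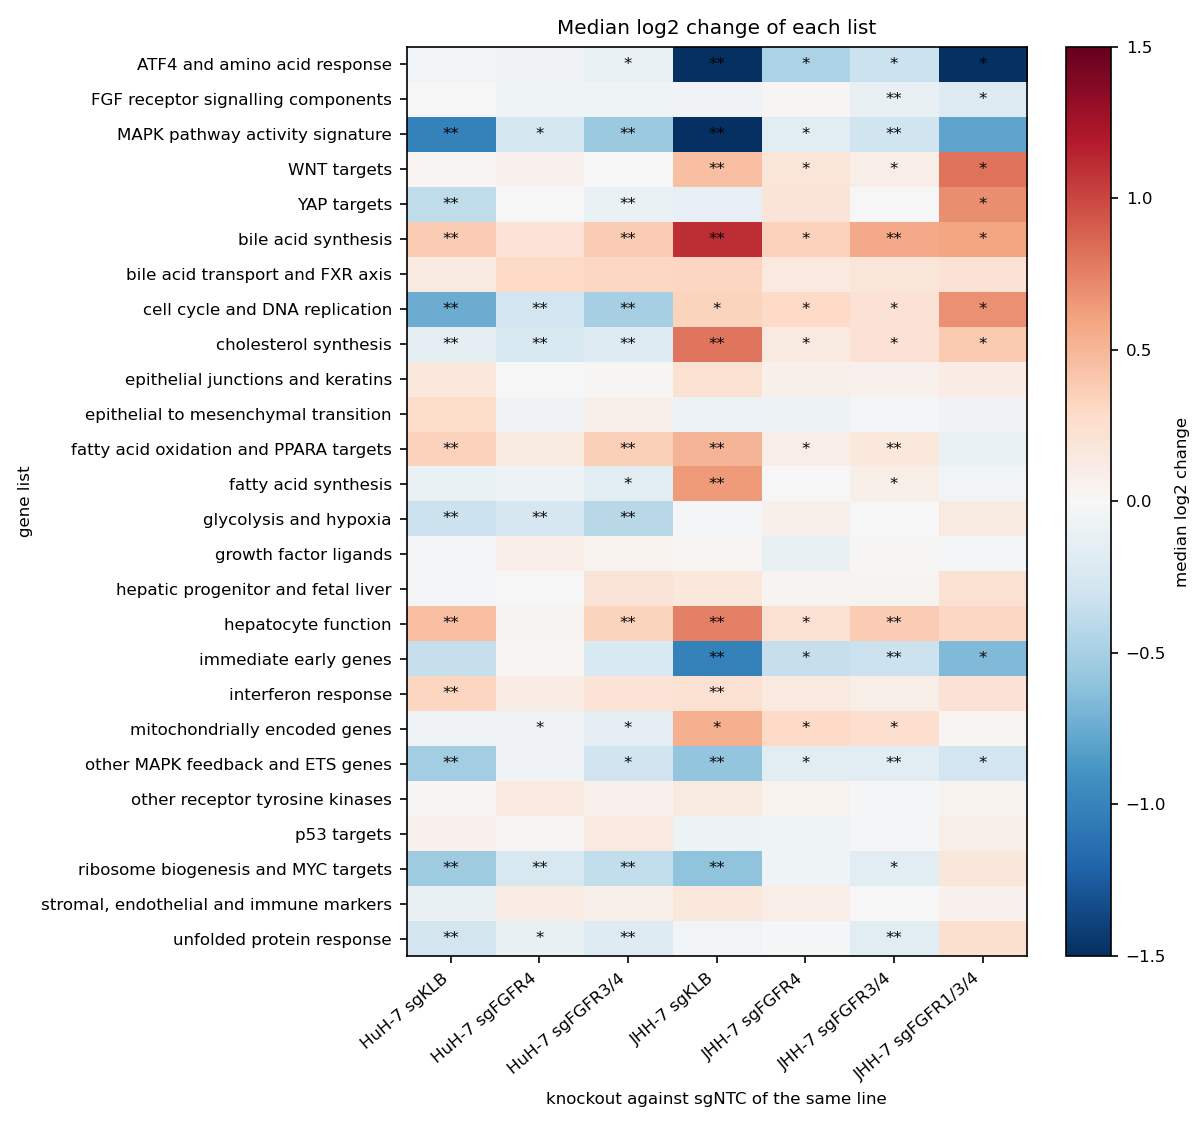
Median log2 change of the members of each gene list in each knockout against sgNTC of its cell line, with colour saturating at 1.5 in either direction. The cell cycle list is negative in the HuH-7 knockouts (-0.74 in sgKLB) and positive in the JHH-7 knockouts (0.33 in sgKLB), and the ATF4 list is lowest in JHH-7 sgKLB (-2.01).

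The lines were then compared through the difference of each knockout's effect, JHH-7 minus HuH-7, over 16731 genes. For sgKLB it passed the threshold in 3296 genes (1639 positive, 1657 negative; 1412 and 1937 with TPM, 1779 and 1524 after quantile normalization). GDF15 differed by -4.25 ± 0.224 and DDIT4 by -4.10 ± 0.218 (both adjusted p 1.84e-11), UNC5B by -3.36 (1.16e-09) and FGF19 by -3.03 ± 0.129 (1.06e-12). The natriuretic peptide NPPB differed by 2.94 ± 0.287 (1.12e-07), the heat shock chaperone HSPA1B by 2.18 (1.55e-09) and DEFB1 by 2.09 (1.43e-05). HSPA1B has a near-identical neighbour, so its reads are uncertain.

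Cell cycle genes differed in 29 of 30 cases, all positive (30 over the list alone, median 1.14, p 7.4e-32, estimated 0.000434), with PCNA at 1.85 and TYMS at 1.73: PCNA went from 197.5 to 111.2 FPKM in HuH-7 and from 85.3 to 174.7 FPKM in JHH-7. The ATF4 list differed in 18 of 19 cases, all negative (median -1.84, p 3.62e-31, estimated 0.000315), since it had 4 rising and 4 falling genes of 19 in HuH-7 sgKLB (median -0.04, p 0.513). Cholesterol synthesis differed positively in 18 of 24 cases with 1 negative (19 and 2, median 0.84, p 2.85e-17, estimated 0.00018). Fatty acid synthesis (7 of 15 positive, median 0.63, p 1.79e-05), bile acid synthesis (5 of 10 positive, median 0.62, p 0.000198), hepatocyte genes (13 of 27 positive, 3 negative; 14 and 4, median 0.37, p 3.6e-05) and WNT targets (6 of 13 positive; 8, median 0.38, p 3.6e-05) were more positive in JHH-7. Immediate early genes (7 of 12 negative; 9, median -0.60, p 9.81e-08), with MYC at -1.59, and mesenchymal transition genes (5 of 12 negative; 6, median -0.47, p 0.000511) were more negative. All of these held with an estimated correlation (p 0.00753 or less), while YAP targets (p 0.0244) and mitochondrial genes (p 6.21e-09) both gave 0.0817. The MAPK signature had 3 of 9 negative and 1 positive (6 and 2 over the list alone, median -0.56) and did not pass camera (p 0.0738) but passed fry (7.32e-05), and DUSP5, outside it, differed by -2.72.

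For sgFGFR4 the lines differed in 689 genes (396 positive, 293 negative; 265 and 440 with TPM). NPPB differed by 1.77 and S100A10 by 1.31 (adjusted p 0.00133 and 0.000224), while CDKN2B differed by -1.77 (2.03e-05), GDF15 by -1.53 (0.000576) and FGF19 by -0.69 (0.00405). ATRX differed by -1.57 (0.0443), a call lost without 10 of the 12 libraries, all but HuH-7 sgNTC replicate 1 and JHH-7 sgNTC replicate 2 (0.0154 to 0.127). The count was 351 without HuH-7 sgNTC replicate 3, 353 without HuH-7 sgFGFR4 replicate 2, 400 without JHH-7 sgNTC replicate 3, and 247 and 356 without JHH-7 sgFGFR4 replicates 1 and 2. Cell cycle genes (21 of 30 positive; 23, median 0.58, p 1.15e-26, estimated 0.00348) and cholesterol synthesis (7 of 24 positive; 15 positive and 1 negative, median 0.33, p 4.64e-08, estimated 0.00727) held. The ATF4 list (p 2.2e-05), immediate early genes (0.00189), hepatocyte genes (0.00905), glycolysis (0.00407), WNT targets (0.0301), YAP targets (0.0301) and mitochondrial genes (9.81e-13) did not hold with an estimated correlation (0.108, 0.0913, 0.1, 0.0869, 0.0881, 0.108 and 0.0869).

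For sgFGFR3/4 the difference passed in 1206 genes (631 positive, 575 negative; 380 and 1007 with TPM, which moved the median of all genes from -0.07 to -0.17). NPPB differed by 1.69, SLC4A11 by 1.61 and GINS2 by 1.38 (adjusted p 0.00108, 0.00198 and 1.34e-05), CDKN2B by -2.21 (3.5e-07) and FGF19 by -1.07 (5.23e-05). HIST2H2AA4 at -1.94 and AKAP9 at -1.81 (0.0195 and 0.0206) lost their calls without HuH-7 sgNTC replicate 3, HuH-7 sgFGFR3/4 replicate 3, JHH-7 sgNTC replicate 3 or JHH-7 sgFGFR3/4 replicate 1, AKAP9 also without JHH-7 sgNTC replicate 1 (up to 0.0697). Leaving out the first 4 of these libraries gave counts of 602, 611, 734 and 642. Cell cycle genes (22 of 30 positive; 24, median 0.69, p 2.53e-32, estimated 0.0012) and cholesterol synthesis (9 of 24 positive; 11, median 0.32, 0.20 with TPM, p 3.3e-08, estimated 0.00664) held. The MAPK signature (median 0.18, p 0.0061), fatty acid synthesis (p 0.00463), glycolysis (p 0.00506), YAP targets (p 0.005) and mitochondrial genes (p 3.16e-12) each gave 0.0561, ribosome biogenesis (p 0.00218) 0.113 and the ATF4 list (p 0.0335) 0.457.

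In sgKLB of both lines 560 genes rose and 406 fell, where 192 and 210 were expected among 13304 genes tested in both (Fisher's exact test, p 7.48e-155 and 8.58e-47, genes not being independent). Another 126 rose in HuH-7 and fell in JHH-7, and 183 did the reverse (211 and 191 expected). sgFGFR3/4 shared 114 rising and 63 falling genes (27.3 and 13.8 expected; 68 to 107 and 30 to 65 without 1 library, the lowest without JHH-7 sgFGFR3/4 replicate 3) and sgFGFR4 19 and 16 (7.35 and 4.55 expected). Opposite changes were 8 and 26 for sgFGFR3/4 (16.3 and 23.1 expected), and for sgFGFR4 1 (CDKN2B, 5.69 expected) and 22 (5.87 expected). The sgFGFR4 overlaps rest on the HuH-7 calls: without HuH-7 sgNTC replicate 2 or 3 or any HuH-7 sgFGFR4 library, only FGFR4 itself moved alike in both lines. The Pearson correlation of log2 changes across genes was 0.276, 0.123 and 0.07 for sgKLB, sgFGFR3/4 and sgFGFR4.

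In camera 8 lists passed in no knockout against sgNTC, among them the p53, epithelial, mesenchymal and progenitor lists. Camera asks whether a list moves more than other genes. fry, which asks only whether its members move on balance 1 way, passed several of these: mesenchymal genes (0.00184) and stromal markers (0.00424) in HuH-7 sgKLB, and mesenchymal and epithelial genes (both 3.31e-06), p53 targets (7.46e-06), receptor tyrosine kinases (0.00435) and growth factor ligands (0.00318) in JHH-7 sgKLB. In sgKLB, genes of bile acid transport and the FXR axis went both ways: 3 rising and 3 falling of 11 in HuH-7 (median 0.13, p 0.631) and 4 and 2 of 11 in JHH-7 (median 0.32, p 0.331), with the FXR target NR0B2 at -0.43 and -1.68 and the transporter SLCO1B1 at 1.05 and 0.89. Hepatic progenitor genes had medians of -0.03 (p 0.874) and 0.16 (p 0.381), with GPC3 rising by 0.63 and 1.10. Epithelial junction genes had 0.16 (p 0.804) and 0.23 (p 0.105), mesenchymal transition genes 0.28 (p 0.062) and -0.09 (p 0.241), p53 targets 0.06 (p 0.907) and -0.08 (p 0.351), and other receptor tyrosine kinases 0.02 (p 0.631) and 0.13 (p 0.315), where EGFR rose by 0.44 and 0.95. Growth factor ligands had -0.02 (p 0.879) and 0.03 (p 0.528), with AREG at -0.38 and -2.26, and stromal, endothelial and immune markers -0.12 (p 0.804) and 0.16 (p 0.792). Median, mean and test differed in sign in HuH-7 sgKLB for progenitor genes (mean 0.01), p53 targets (test downward), receptor tyrosine kinases (mean -0.03), growth factor ligands (mean 0.04), WNT targets (median 0.03, mean -0.11, p 0.804) and stromal markers (mean 0.14), and in JHH-7 sgKLB for growth factor ligands (mean -0.25). The remaining lists of sgKLB did not pass camera: FGF receptor components (-0.01, p 0.673, in HuH-7 and -0.05, p 0.298, in JHH-7), immediate early genes (-0.35, p 0.275), fatty acid synthesis (-0.10, p 0.399) and mitochondrial genes (-0.06, p 0.489) in HuH-7, and glycolysis (-0.02, p 0.463), the unfolded protein response (-0.04, p 0.528) and YAP targets (-0.12, p 0.351) in JHH-7.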

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

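Tests on TPM, on length and GC corrected values and on labels kept by other splits were chosen after the data were seen. So were difference tests without 1 library for genes not so treated above. The first 4 paragraphs give knockout effects that differed between lines in a direct test (JHH-7 minus HuH-7, n = 3 per group). Whether unequal target mRNA falls (FGFR4, 0.57 in sgFGFR3/4) add to them was not tested.

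For sgKLB 3296 genes differed. More positive in JHH-7 were GSTA1 (3.52), GAST (3.16), NPPB (2.94), UGT2B10 (2.32), HSPA1B (2.18), DEFB1 (2.09), SULT2A1 (2.00), GSTA2 (1.99), RRM2 (1.60), SYT12 (1.56), PIMREG (1.52), CDC45 (1.46), LGALS14 (1.42), H19 (1.18) and FGFR3 (0.57). More negative were PON1 (-0.91), UGT2B4 (-0.93), KLHL24 (-1.45), CLTRN (-1.55), DUSP5 (-2.72), FGF19 (-3.03), UNC5B (-3.36), IGFBP1 (-3.72), DDIT4 (-4.10) and GDF15 (-4.25). GSTA1 and GAST in HuH-7 and LGALS14 and SYT12 in JHH-7 had group means below 1 FPKM, so for them the difference says mainly that the gene is expressed in 1 line. List medians differed for the cell cycle (1.14), cholesterol synthesis (0.84), fatty acid synthesis (0.63), bile acid synthesis (0.62), WNT targets (0.38), hepatocyte function (0.37), mesenchymal transition (-0.47), immediate early genes (-0.60) and the ATF4 list (-1.84).

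For sgFGFR4 689 genes differed: NPPB (1.77), S100A10 (1.31), GSTA1 (1.30), TK1 (1.25), UGT2B10 (1.18), SULT2A1 (1.04), PIMREG (0.96), RRM2 (0.95), GSTA2 (0.92), SPTLC3 (0.84), CDC45 (0.78), FGF19 (-0.69), KLHL24 (-0.78), DDIT4 (-0.82), DUSP5 (-1.04), BEX2 (-1.17), GDF15 (-1.53), ATRX (-1.57), CDKN2B (-1.77) and IGFBP1 (-2.12), and the medians of cholesterol synthesis (0.33) and the cell cycle (0.58). For sgFGFR3/4 1206 genes differed: NPPB (1.69), SLC4A11 (1.61), GSTA1 (1.45), LGALS14 (1.45), GINS2 (1.38), CDC45 (1.30), PIMREG (1.17), PLCXD2 (1.16), RRM2 (1.06), UGT2B10 (0.89), ETV4 (0.68), SULT2A1 (0.61), FGFR4 (0.57), FGFR3 (0.30), DUSP5 (-0.48), SERPINF2 (-0.56), FGF19 (-1.07), UGT2B4 (-1.12), KLHL24 (-1.14), GDF15 (-1.33), IGFBP1 (-1.35), CLTRN (-1.51), AKAP9 (-1.81), HIST2H2AA4 (-1.94) and CDKN2B (-2.21), and the medians of cholesterol synthesis (0.32) and the cell cycle (0.69).

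Some of these differences rest on single libraries, ATRX, AKAP9 and HIST2H2AA4 as given above and others as follows. In brackets are the number of the 12 libraries whose removal ended the call and the highest adjusted p without 1 of them. For sgKLB they are H19 (2, 0.0629) and PON1 (8, 0.111). For sgFGFR4 they are PIMREG (7, 0.101), GSTA2 (6, 0.0595), SPTLC3 (8, 0.123), CDC45 (7, 0.0847), KLHL24 (7, 0.138), DDIT4 (9, 0.112) and BEX2 (10, 0.107). For sgFGFR3/4 they are LGALS14 (2, 0.0527), UGT2B10 (3, 0.0552), SULT2A1 (3, 0.068), FGFR3 (5, 0.084), DUSP5 (4, 0.0757) and IGFBP1 (8, 0.102). FGFR3 also lost its call with TPM (0.184) and quantile normalization (0.148).

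Of 100 splits of the libraries drawn in both lines together, 1 reached the real 3296 genes for sgKLB (the real one, highest other 3099). It was 2 for sgFGFR4 (real 689, highest other 1227) and 4 for sgFGFR3/4 (real 1206, highest other 2585). Splits keeping or exchanging a line's labels hold guide effects, so the shares cannot exclude chance or other library differences. Other splits above the real count kept JHH-7 and exchanged HuH-7 labels (1227 for sgFGFR4, 1879 for sgFGFR3/4). For sgFGFR3/4, others kept HuH-7 and mixed JHH-7 labels (2585) or mixed the labels of both (1788). Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. All but the real split mix both groups, so any group difference can lower their counts. The real count and the highest other were 2591 and 0, 546 and 2, and 2371 and 1 for HuH-7 sgKLB, sgFGFR4 and sgFGFR3/4 against sgNTC, 238 and 1 for sgFGFR3/4 against sgFGFR4, and 2463 and 2, and 81 and 1, for sgKLB against sgFGFR4 and sgFGFR3/4. In JHH-7 they were 4781 and 1, 637 and 0, 529 and 7, and 5963 and 3 for sgKLB, sgFGFR4, sgFGFR3/4 and the sgFGFR1/3/4 group against sgNTC, 4826 and 2 for sgFGFR1/3/4 against sgFGFR3/4, and 2900 and 1, and 5346 and 1, for sgKLB against sgFGFR4 and sgFGFR1/3/4. For JHH-7 sgFGFR3/4 against sgFGFR4, 3 of the 10 splits gave at least the real 2 genes (highest other 6).

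HuH-7 sgFGFR4 called 546 genes, the rising ones with long transcripts. Removing each library's trend with length and GC content left 364 genes, 107 rising (from 304) and 257 falling (from 242). Of the 242 falling genes 165 stayed past the threshold, with their median going from -0.361 to -0.293, which argues against that trend as their whole cause. Of the 304 rising genes only 78 stayed and their median went from 0.592 to 0.349 (SD 0.274 and 0.303 across genes), so for them the trend and an effect of the guide cannot be told apart: most calls ended, but more than 50% of the median change remained. Without sgNTC replicate 3, the library with the fewest genes detected, the count was 2, so a candidate explanation is that this control differs from the other controls. Other libraries had a similar effect when left out (down to 1 gene), so the count is not tied to that control alone.

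JHH-7 sgFGFR1/3/4 stood apart from sgFGFR3/4 in 4826 genes. Removing length and GC trends left 4154, against such a trend as the whole cause. Of the 4826 genes 51.5% moved the same way in sgKLB against sgFGFR4 (66.1% of the 398 changed by at least 1 on the log2 scale). A batch of sgFGFR1/3/4, its lower FGFR3 and FGFR4, and loss of FGFR1 acting on genes that KLB loss changes cannot be told apart. All 3 libraries share them, and 51.5% lies near an even split.

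The cell cycle list fell in HuH-7 sgKLB (median -0.74) and rose in JHH-7 sgKLB (0.33). Scaling cannot be told apart from a guide effect. Either scaling moved the median of all genes by only 0.062 (HuH-7) and 0.006 (JHH-7) at most. The list medians stayed at -0.681 or below and 0.332 or more. Removing length and GC trends, which raised the JHH-7 count to 5362 genes, left 0.302. The test of the difference (adjusted p 0.000434 with an estimated correlation) only restates the pattern. A different response of the lines to loss of KLB and a different cell density or growth phase at harvest cannot be told apart, the latter not being measured. The rise within JHH-7 did not hold with an estimated correlation (0.236).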

How the results depend on the processing

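TPM scaling, the length and GC correction, quantile normalization of the lists and leaving out the sgFGFR1/3/4 libraries were chosen after seeing the data; the other alternatives were planned. Of 17629 values of named genes and lists under an alternative, 15738 (89.3%) kept direction and side of the threshold, 1867 lost their call, 15 gained one and 9 changed sign. Calls lost were 43 of 1309 with TPM, 104 of 1309 with quantile normalization, 173 of 1130 without the low-value filter, 119 of 1309 with replicate blocks, 78 of 948 after the length and GC correction, 176 of 945 with only the groups compared, 11 of 1130 with a pseudocount of 0.1, 1 of 1037 with the stricter filter, 26 of 282 without the sgFGFR1/3/4 libraries, 83 of 179 with an estimated correlation, 8 of 179 with fry and 1045 of 7872 with 1 library left out. The planned count-based normalization and count-based test were not run, since the tables hold FPKM and no counts.

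Requiring a change of at least 1 on the log2 scale gave 224, 30 and 147 genes for HuH-7 sgKLB, sgFGFR4 and sgFGFR3/4 against sgNTC, 23 for sgFGFR3/4 against sgFGFR4, and 228 and 15 for sgKLB against sgFGFR4 and sgFGFR3/4. In JHH-7 it gave 864, 47, 56 and 814 for sgKLB, sgFGFR4, sgFGFR3/4 and the sgFGFR1/3/4 group against sgNTC, 398 for sgFGFR1/3/4 against sgFGFR3/4, and 384 and 486 for sgKLB against sgFGFR4 and sgFGFR1/3/4. Line differences were 880, 97 and 183 for sgKLB, sgFGFR4 and sgFGFR3/4. These are lower by construction. Shared genes then numbered 2, 58 and 13 for HuH-7 sgKLB with sgFGFR4, sgKLB with sgFGFR3/4 and sgFGFR4 with sgFGFR3/4, and in JHH-7 38, 44 and 356 for sgKLB with sgFGFR4, sgFGFR3/4 and sgFGFR1/3/4, 23 for sgFGFR4 with sgFGFR3/4, and 40 and 39 for sgFGFR4 and sgFGFR3/4 with sgFGFR1/3/4. Between lines they were 80, 1 and 8 for sgKLB, sgFGFR4 and sgFGFR3/4.

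Without the low-value filter, where more genes are tested, the counts were 1, 1433, 134, 1592 and 20 for HuH-7 sgFGFR4, sgFGFR3/4, sgFGFR3/4 against sgFGFR4, and sgKLB against sgFGFR4 and sgFGFR3/4, 337, 263 and 4 for JHH-7 sgFGFR4, sgFGFR3/4 and sgFGFR3/4 against sgFGFR4, and 346 and 732 for the sgFGFR4 and sgFGFR3/4 line differences. With only the groups compared, which leaves fewer libraries to estimate the spread, they were 1, 999, 87 and 8 for HuH-7 sgFGFR4, sgFGFR3/4, sgFGFR3/4 against sgFGFR4 and sgKLB against sgFGFR3/4, and 87 and 128 for JHH-7 sgFGFR4 and sgFGFR3/4. Without the sgFGFR1/3/4 libraries these last counts were 409 and 294. Replicate blocks gave 1 for HuH-7 sgFGFR4, 119 for sgFGFR3/4 against sgFGFR4 and 9 for sgKLB against sgFGFR3/4. The length and GC correction gave 440 and 206 for those last 2 comparisons and 4 for JHH-7 sgFGFR3/4 against sgFGFR4, where the stricter filter and the pseudocount of 0.1 each gave 1. For HuH-7 sgFGFR4, quantile normalization gave 96 and the stricter filter 1018. For blocks, correction, quantile normalization, the stricter filter and the pseudocount the cause was not tested.

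Lists past the threshold fell with an estimated correlation to 4 of 7 for HuH-7 sgFGFR4, 6 of 10 and 5 of 10 for sgKLB against sgFGFR4 and sgFGFR3/4, 0 of 11, 8 of 15 and 0 of 9 for JHH-7 sgFGFR4, sgFGFR3/4 and sgFGFR1/3/4, 0 of 8 for sgFGFR3/4 against sgFGFR4, 0 of 6 for sgFGFR1/3/4 against sgFGFR3/4, 7 of 11 for sgKLB against sgFGFR1/3/4, and 2 of 9 for the sgFGFR4 and the sgFGFR3/4 line differences. With fry they rose to 12 for HuH-7 sgFGFR4, 23, 18 and 17 for JHH-7 sgKLB, sgFGFR4 and sgFGFR1/3/4, 19 for sgFGFR1/3/4 against sgFGFR3/4, 21 for sgKLB against sgFGFR1/3/4, and 21 and 14 for the sgKLB and sgFGFR4 line differences. The tools ask different questions of correlated genes, and the cause was not tested further.

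Leaving out 1 library gave 1809 to 2240 genes for HuH-7 sgKLB, 1 to 1224 for sgFGFR4, 1150 to 2751 for sgFGFR3/4, 99 to 142 for sgFGFR3/4 against sgFGFR4, 1221 to 1869 and 3 to 181 for sgKLB against sgFGFR4 and sgFGFR3/4. JHH-7 gave 4020 to 4542 for sgKLB, 222 to 845 for sgFGFR4, 259 to 426 for sgFGFR3/4, 4734 to 5578 for sgFGFR1/3/4, 1 to 4 for sgFGFR3/4 against sgFGFR4, 3651 to 5026 for sgFGFR1/3/4 against sgFGFR3/4, and 2062 to 2379 and 4218 to 4697 for sgKLB against sgFGFR4 and sgFGFR1/3/4. Line differences ran 2871 to 3091, 247 to 971 and 602 to 1618 for sgKLB, sgFGFR4 and sgFGFR3/4.

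Signs changed after quantile normalization for the mitochondrial list in HuH-7 sgFGFR4 (median 0.051) and sgFGFR3/4 (0.022), for MT-ND4L in HuH-7 sgFGFR3/4 (0) and for MT-ND4 in JHH-7 sgFGFR1/3/4 (0.067). After the length and GC correction they changed for MT-ND3 in HuH-7 sgKLB against sgFGFR4 (0.119), NR5A2 and MET in JHH-7 sgFGFR1/3/4 against sgFGFR3/4 (both -0.012), and FGF19 (-0.178) and ME1 (0.085) in sgKLB against sgFGFR1/3/4; the cause was not tested.

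Replicate numbers did not pair the libraries: residuals of libraries with the same number correlated at -0.397 to 0.19 in HuH-7 and -0.481 to 0.129 in JHH-7. At 14.3 M to 27.4 M fragments, 1 fragment on a 2 kb transcript equals 0.0217 to 0.0421 FPKM, so genes under the filter of 1 FPKM, such as FGFR2 in HuH-7, rest on few fragments.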

Other observations

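The gene families, their members and the ATF4 mRNA test were chosen after the results were seen. Family p-values are thus not those of fixed lists. The prediction for the tRNA synthetases was written before their values were read.

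Of 6 families read, UDP-glucuronosyltransferases, rose in every knockout of both lines with 0 falling: 5, 4 and 5 of 7 measured genes in HuH-7 sgKLB, sgFGFR4 and sgFGFR3/4 (medians 0.81, 0.62 and 1.07) and 7, 5, 3 and 8 of 9 in JHH-7 sgKLB, sgFGFR4, sgFGFR3/4 and the sgFGFR1/3/4 group (medians 0.75, 0.46, 0.42 and 1.35). The adjusted p with an estimated correlation was 0.0115 to 0.027, and the medians stayed positive with TPM and quantile normalization. The 4 calls in HuH-7 sgFGFR4 rest on a count that fell to 1 to 4 genes without any of 5 libraries (UGT2B4 lost its call in 5 of 6 fits). Genes of the UGT1A locus share exons, so they are not separate readings. The difference between lines did not pass for sgKLB (p 0.135).

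Other drug metabolism families varied. Glutathione transferases and sulfotransferases rose in JHH-7 sgKLB (8 of 9 and 6 of 10 genes, medians 0.679 and 0.772), sgFGFR4 (4 and 1, 0.423 and 0.3) and sgFGFR3/4 (5 and 2, 0.472 and 0.458), with an estimated p of 0.0143 or less. In sgFGFR1/3/4 (6 and 3, 1 and 2 falling, 0.678 and 0.223) it was 0.0957 and 0.334 (preset 0.00751 and 0.276). In HuH-7 sgKLB, sgFGFR4 and sgFGFR3/4 the sulfotransferase medians were 0.413, 0.251 and 0.61 (0.0151, 0.175 and 0.0212) and those of glutathione transferases 0.245, -0.099 and 0.007 (0.137, 0.229 and 0.911; the last -0.011 after quantile normalization). Cytochrome P450 families 1 to 4 passed with an estimated correlation only in JHH-7 sgKLB (median 0.652, 0.0186; 0.0602 to 0.924 in the other 6 knockouts) and at the preset one also in HuH-7 sgKLB (0.0302) and JHH-7 sgFGFR3/4 (0.0359), and the medians of JHH-7 sgFGFR4 (0.035) and sgFGFR1/3/4 (-0.025) changed sign, to -0.023 after quantile normalization and 0.018 with TPM.

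Heat shock proteins and their partners moved in opposite directions in sgKLB of the lines. In HuH-7 sgKLB 8 of 15 fell and 0 rose (median -0.28, estimated p 0.00346), and in JHH-7 sgKLB 10 rose and 1 fell (median 0.65, estimated p 0.0432), with a difference between lines of 0.91 (estimated p 0.0021). In JHH-7 sgFGFR1/3/4 14 of 15 rose (median 1.11, estimated p 0.0264). Against sgFGFR3/4, 13 of 15 rose in that group and 0 fell (median 1.01, preset p 7.57e-10, estimated p 0.0527), and in JHH-7 sgFGFR4 and sgFGFR3/4 only 2 and 1 of 15 rose (medians 0.21 and 0.13, estimated p 0.128 and 0.196). In HuH-7 5 and 7 fell in these knockouts (medians -0.14 and -0.20, estimated p 0.027 and 0.0115). All these signs held with TPM and quantile normalization, but the last 2 medians shrank (TPM -0.06 and -0.09, quantile -0.06 and -0.12).

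The fall of the ATF4 list in JHH-7 sgKLB raised the hypothesis that ATF4 activity itself is lower. It predicts that ATF4-dependent genes outside the fixed list fall too, and the cytosolic aminoacyl-tRNA synthetases were tested: 17 of 20 fell and 0 rose (median -0.87, estimated p 0.00214). It fell less in the other JHH-7 knockouts, where the ATF4 list fell too: sgFGFR4 (3 of 20, median -0.13, estimated p 0.0168), sgFGFR3/4 (1, -0.16, 0.0175) and sgFGFR1/3/4 (10 with 1 rising, -0.46, 0.0264). It also fell slightly in HuH-7 sgFGFR3/4 (7, -0.14, -0.03 with TPM, 0.0115) and in HuH-7 sgKLB (5, -0.14, -0.07 with TPM, 0.013), where the ATF4 list did not pass camera (median -0.04, p 0.513). Lower ATF4 activity may be a candidate explanation in JHH-7, though protein was not measured and lower demand for amino acids would look alike. Whether ATF4 mRNA falls in step with its targets cannot be told apart from a change at the protein level: ATF4 itself changed by -0.996, against a median of -2.08 for the other list members. The difference between lines of the synthetases in sgKLB was -0.63 (estimated p 0.000475).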
